A study of Mus musculus with 8 samples.

How the data were processed

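H3K27ac ChIP-seq was made from 4 libraries of flow-sorted CD8+ T cells from the spleen of infected C57BL/6 mice, 2 WT and 2 Pac1-/-, with the antibody ab4729 (Abcam), 15 cycles of PCR and fragments of about 250 bp, per the labels' protocols. Genotype and replicate number came from the sample labels. A further 4 input libraries are named there and were not used here. The submitters' processing notes name CASAVA 1.4, Bowtie2 2.3.5, MACS2 2.1.2 and the mouse build mm10, without their order or settings. The deposited data are 1 list of single-base summits per library, each summit with the −log10 of its q value as its score, as the authors' peak caller gave it. The unit was read from the values. The form of the lists is that of MACS2, and the smallest score of each list lies just above 1.30103, the −log10 of 0.05. How the inputs, duplicates and repeat regions were treated is not given in the sources used here. Scores were not scaled between libraries and served only to describe, rank or filter summits within a list. Lists were called per library, so a summit absent from a list may lie just under the limit. Read depth is unknown, and no interval that needs it is given.

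Summits on autosomes 1 to 19, X and Y were extended 500 bp each way, and overlapping windows of the 4 libraries were merged into regions. A library was present in a region if it had a summit there. KO-only and WT-only regions were counted for the genotype and for the other 2 of the 3 splits of 4 libraries into pairs. Library pairs were compared by the Jaccard index of regions. Genes came from an NCBI RefSeq table of GRCm38.p6, the assembly of mm10, with 21883 protein-coding genes; 513 of 515 genes in the lists matched it. The table used here gives gene bounds without strand or exons. The planned distance to a transcription start was therefore replaced by 2 kb from either gene end, and the planned nearest start by the nearest gene body within 100 kb. A region was placed, and its distance to a gene taken, by the mean position of its summits. The planned test of 19 motif consensuses needs a genome sequence and was not run.

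Before the data were examined, 20 gene lists were fixed, covering effector function, exhaustion, memory, T cell identity, MAP kinase signalling, NuRD, acetyltransferases, interferon response, cell cycle, metabolism, cytokine receptors, adhesion, markers of other cells and housekeeping genes. KO-only against WT-only regions of each list were tested by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the lists and odds ratios with 0.5 added to each cell. Summits per gene locus were tested with limma (trend) on the log2 of summits plus 0.5, scaled by library total, at loci with at least 4 summits, and lists with camera at a preset correlation of 0.01. Genes named in the text were chosen by a rule fixed in advance: Dusp2, up to 4 genes per list with the most genotype-specific regions, the 10 strongest KO-only and WT-only regions, the 8 loci leaning most each way, the 8 with the most summits and the 10 with the smallest limma p. Other members of the effector and B cell lists were named after their values were seen. So were list genes with a gene-end summit in 1 genotype alone and genes in windows of 500 kb. The same holds for Id2, for the Y genes Kdm5d, Eif2s3y, Uty and Ddx3y, and for the regions without a nearby summit of the other genotype. Single values of 2 list genes are not reported here.

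Scripts were tested on simulated data. Merging recovered all 14000 shared, 1000 KO-only and 700 WT-only simulated sites. These were set far apart, with a jitter of 100 bp (SD) and no missed summits. Full recovery was therefore built in, and neighbouring or shifted summits were not tested. For limma a first simulation that drew Poisson counts recovered none of the changed loci, and it was exchanged for one that draws each site per library. With no change this gave 240 calls in 9159 loci. With a 2-fold change at 198 loci, 65.2% were recovered beside 310 false calls, and a 4-fold change was recovered at all 200 beside 216. Without the trend, 1 locus of 9154 was called with no change and 45% of the 2-fold changes were recovered beside 7 false calls, but at a 4-fold change 195 of 200 were recovered beside 152 false calls. Camera made 32 false calls in 900 list tests. It recovered the effector list in all 50 simulations with sites multiplied by 1.5, rounded, and at least 1 site added per gene. The change was thus larger at genes with few sites. Added sites were nearly always present in both simulated Pac1-/- libraries, so smaller or less steady changes were not tested. Loss of each replicate, other windows, score limits, list lengths, chromosomes, gene distances, pseudocounts and limma settings were tried as alternatives. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.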

Results

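Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by ChIP-seq in CD8+ T cells sorted by flow cytometry from the spleens of C57BL/6 mice. The mice had been infected for 30 days with LCMV clone 13, a virus strain that sets up a chronic infection. Cells were either wild type (WT) or lacked PAC1 (Pac1-/-), the nuclear phosphatase of MAP kinases encoded by Dusp2, with 2 libraries per genotype. The data are 1 list of H3K27ac summits per library, each summit carrying the authors' score, the −log10 of its q value. Read depth is unknown, so precision rests on the list lengths and on the agreement of replicates. On the autosomes, X and Y the WT lists held 17997 and 20105 summits and the Pac1-/- lists 18892 and 18538, or 19051 ± 1491 against 18715 ± 250 (SD, n = 2 each). Median scores were 27.4 and 25.6 in WT and 33.8 and 33.6 in Pac1-/-. A summit lay within 2 kb of an annotated end of 10347 and 10520 protein-coding genes in WT and of 10335 and 10334 genes in Pac1-/-. Nothing in the labels says that replicates came from separate animals, so every spread below is the spread between these samples, which may be technical.

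The targeted gene was examined first as a check of the labels. Dusp2 lies at chromosome 2, 127336159 to 127338377 (mm10). Both WT libraries had a summit inside the gene, at 127336433 with a score of 89.3 and at 127336383 with a score of 128, and neither Pac1-/- library had one there. Both Pac1-/- libraries instead had summits on either side of the gene. These were at 127333712 and 127333654, 2447 and 2505 bp before its lower coordinate, and at 127338486 and 127338539, 109 and 162 bp past its upper coordinate. A further pair of summits at 127317973 and 127318000 was present in WT alone, with scores of 96.1 and 134. All 4 libraries shared a summit near 127315131, about 21028 bp before the gene. Summits assigned to Dusp2 as their nearest gene body numbered 3 and 4 in WT and 4 and 4 in Pac1-/-, a count that leaves out some of the summits listed above. Which part of the gene was deleted is not given in the sources used here, so the missing summit separates the genotypes as labelled without giving a level of Dusp2.

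**Figure D1:**
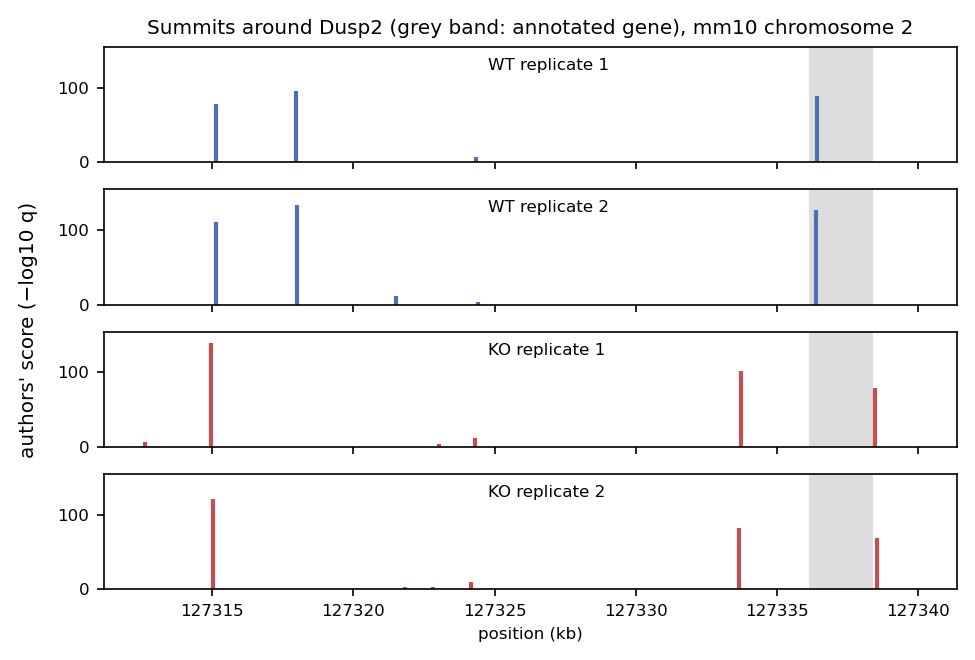
Position (kb, mm10 chromosome 2) and authors' score (−log10 q) of each summit around Dusp2, 1 panel per library, with the annotated gene as a grey band. Only the WT libraries have a summit in the band, at 127336433 and 127336383, and only the Pac1-/- libraries have the flanking summits.

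The first comparison asked how far the acetylated regions of the 2 genotypes differ. Summits of the 4 libraries merged into 23637 regions, of which 14283 (60.4%) had a summit in every library. KO-only regions, found in both Pac1-/- libraries and neither WT library, numbered 1073, and WT-only regions, the mirror, numbered 1083. Splitting the same libraries by replicate number gave 125 and 247 such regions, and the crossed split gave 99 and 319, so 2156 regions followed the genotype against 372 and 418 for the mixed splits. Libraries of 1 genotype also shared more of their regions, with a Jaccard index of 0.781 between the WT and 0.827 between the Pac1-/- libraries. The 4 pairs of unlike genotype reached 0.729 ± 0.00692 (SD, n = 4 pairs), and the difference of the means was 0.075. Genotype gave the highest of 3 possible splits on both measures, and the smallest p an exact test over 3 splits allows is 0.333. Many of the genotype-specific summits were weak. Their median rank within a library was percentile 16.03 of scores for KO-only and 23.1 for WT-only regions, against 61.3 for regions of all 4 libraries. No summit of the other genotype lay within 5 kb of 662 KO-only (61.7%) and 633 WT-only regions (58.4%).

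**Figure D2:**
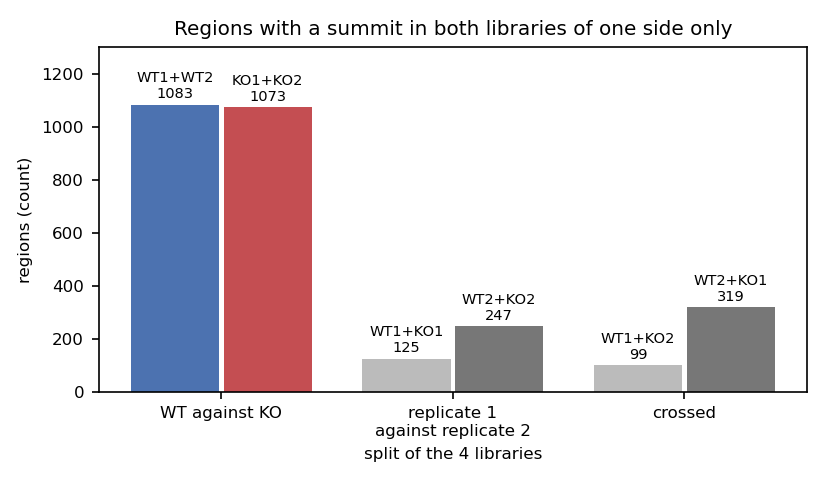
Number of regions with a summit in both libraries of one side and in neither of the other, for the 3 ways to split the 4 libraries into pairs (bars, count of regions, 1 bar per side). Genotype gives 1083 and 1073, replicate number 125 and 247, and the crossed split 99 and 319.

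Genotype-specific regions lay mostly away from gene ends. A summit within 2 kb of an annotated gene end was found in 137 KO-only regions (12.8%, Wilson 95% interval 10.9 to 14.9) and 193 WT-only regions (17.8%, 15.7 to 20.2), against 8693 (60.9%) of the regions of all 4 libraries. KO-only regions were at gene ends less often than WT-only regions (odds ratio 0.676, 95% interval 0.533 to 0.856, Fisher's exact test, two-sided, p = 0.00122). The call ended with a distance limit of 1 kb (odds ratio 0.833, exact p = 0.214), with windows of 250 bp (0.819, exact p = 0.0533) and with the top 10000 summits of each list (0.851, exact p = 0.296). With the top 10000 summits the shares at gene ends were 33.1% of KO-only and 36.7% of WT-only regions. Distance from gene ends was thus not separated from the low scores of these regions. At the level of genes, 100 had a gene-end summit in both Pac1-/- libraries alone and 133 in both WT libraries alone, with 9915 genes in all 4, against totals of 57 and 57 genes in the mixed splits. Genes of the fixed lists with a gene-end summit in Pac1-/- alone included Gzma and Gzmk (granzymes of cytotoxic granules), Klrg1 (a receptor of differentiated effector cells), and Ccr2, Cxcr6, Itga1, Itgax, Cd101 and Dapl1. Those with one in WT alone included Pax5, Ebf1, Spib and Blnk (B cell genes), and Bcl11a, Cebpa, Ly86, Ccr8 and Ptpn22.

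Loci of effector function carried more acetylated sites in the Pac1-/- libraries. Summit counts do not separate a change within CD8+ T cells from a change in the cells sorted. The list of 36 genes for cytotoxic molecules, inflammatory cytokines, killer lectin-like receptors and their regulators held 30 KO-only and 4 WT-only regions (odds ratio 7.05, 95% interval 2.61 to 19.05, Fisher's exact test, two-sided, adjusted p = 5.13e-05 over 20 lists). Its loci held 86.5 ± 2.12 summits in WT and 129.5 ± 4.95 in Pac1-/- (SD, n = 2 each), a ratio of 1.497. Both Pac1-/- libraries were above both WT libraries at 19 genes and below at 2 (Stat4 and Il2rb), and the libraries overlapped at 15. Chance alone would put 16.7% of genes without ties in each direction. The mixed splits gave 1 and 0 regions, and 1 and 1, on their sides. A KO-only region was assigned to 23 of the genes. In the same libraries B cell marker loci held 35.5 ± 2.12 summits in WT and 9 ± 1.41 in Pac1-/-, and NK cell marker loci 12.5 ± 0.707 and 19.5 ± 3.54 (SD, n = 2 each).

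Among single effector loci, summits numbered 5 and 7 in WT and 11 and 11 in Pac1-/- at Fasl, the death ligand of cytotoxic cells, which held 4 KO-only regions and 1 WT-only region. Ifng, the gene of interferon gamma, had 3 and 6 against 7 and 8. The pore-forming Prf1 had 2 and 2 against 4 and 4, Gzmb 3 and 3 against 5 and 5, Gzmk 1 and 0 against 4 and 3, and Gzma none in WT against 2 and 2. Receptors of the chromosome 6 cluster gave 1 and 2 against 6 and 3 summits at Klrk1 and 1 and 1 against 3 and 3 at Klrc1. Transcription factors of effector cells gave 3 and 4 against 10 and 5 at Eomes, 7 and 7 against 10 and 12 at Runx3, 3 and 3 against 4 and 5 at Tbx21, and 3 and 3 against 5 and 4 at Prdm1. Stat4 had 7 and 10 against 6 and 5, and Il18r1 4 and 5 against 5 and 5, and the counts at Stat4 did not differ once summits with scores under 5 were left out. The KO-only regions included chromosome 13, 113099136 to 113101231, across 1 end of Gzma, which ends at 113100981, and chromosome 6, 129622373 to 129622460, inside Klrk1 and 1487 bp from its end by mean summit position. Others, by the same measure, were chromosome 1, 161774395 to 161775174, 5907 bp outside Fasl, and chromosome 10, 118406939 to 118407117, 34018 bp outside Ifng. Exon boundaries were not used here. Scores of these KO-only summits were low, from 1.72 at Gzmk to 27.6 at Klrk1. Fisher's test counts regions of these 4 libraries, several of them near 1 gene, and does not treat replicates as the unit.

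**Figure D3:**
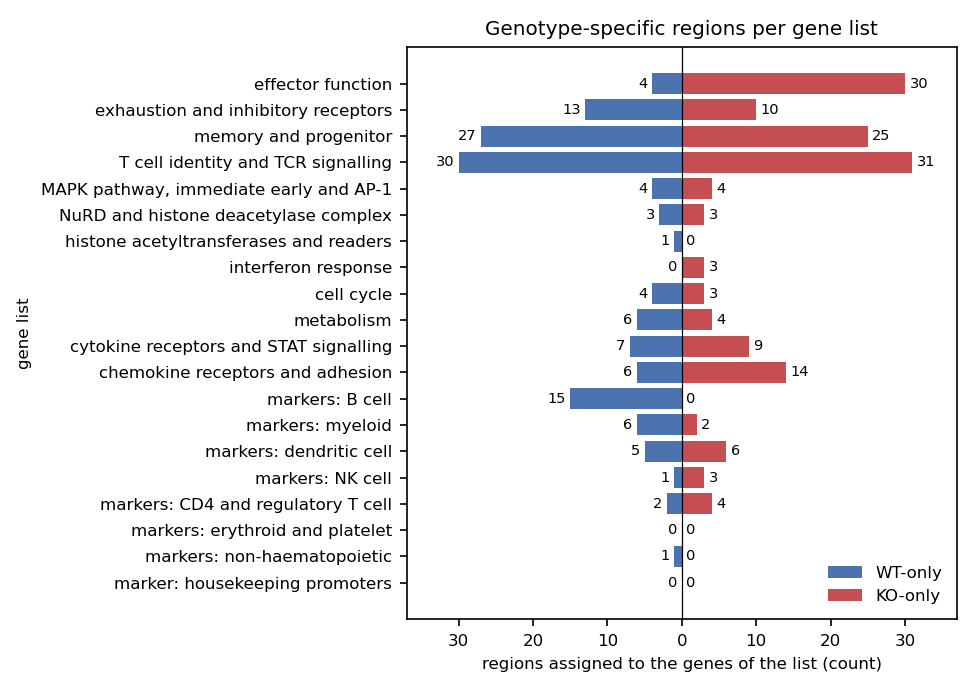
KO-only regions (bars to the right) and WT-only regions (bars to the left) assigned to the genes of each of 20 lists, as counts. The effector list has 30 against 4 and the B cell list 0 against 15.

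B cell marker loci went the other way. The 18 genes held 0 KO-only and 15 WT-only regions (odds ratio 0.0322, 95% interval 0.00193 to 0.539, Fisher's exact test, two-sided, adjusted p = 0.000582), and their summits fell from 35.5 ± 2.12 in WT to 9 ± 1.41 in Pac1-/- (SD, n = 2 each). Both Pac1-/- libraries were below both WT libraries at 9 genes, above at 0, and overlapped at 8, and 1 gene had no summit. Pax5, the regulator of B cell identity, had 6 and 4 summits in WT and none in Pac1-/-, Ebf1 6 and 5 against 2 and 0, Spib 2 and 3 against none, and Ciita, the activator of MHC class II genes, 2 and 2 against none. The call ended with the top 10000 summits of each list (0 against 3 regions, exact test, adjusted p = 0.839) and when presence needed a score of 5 (0 against 7, exact test, adjusted p = 0.207).

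**Figure D4:**
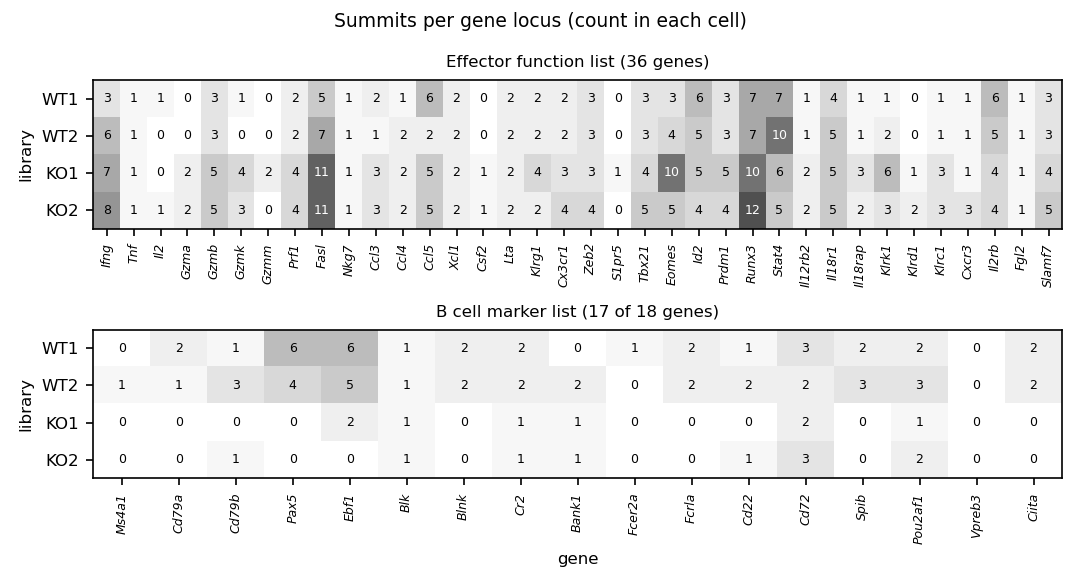
Summits per gene locus in each library (rows), as the count in each cell with darker grey for more, for the 36 genes of the effector list (top) and 17 of the 18 B cell markers (bottom). At Fasl the counts are 5, 7, 11 and 11, and at Pax5 6, 4, 0 and 0.

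The other 18 lists did not pass the test. The list of chemokine receptors and adhesion held 14 KO-only and 6 WT-only regions (odds ratio 2.28, 95% interval 0.900 to 5.77, exact test, adjusted p = 0.501), with 3 KO-only regions each at the integrin genes Itgb1 (1 and 2 summits in WT, 5 and 6 in Pac1-/-) and Itga1 (none in WT, 3 and 3 in Pac1-/-), and 2 WT-only regions at Ccr8 (2 and 2, none in Pac1-/-). Cd44 had 4 and 4 against 5 and 5. The exhaustion list held 10 and 13 regions. Within it Tox, a driver of the exhausted state, had 4 and 6 summits in WT and 11 and 9 in Pac1-/-, a direction that turned when summits were assigned by the nearest gene end, and Bhlhe40 had 5 and 7 against 9 and 7. Nfatc1 had 13 and 14 against 10 and 11, and Tnfrsf1b 10 and 10 against 8 and 7. Memory and progenitor genes held 25 KO-only and 27 WT-only regions, with 23 and 27 summits against 21 and 24 at Foxp1, 17 and 20 against 22 and 20 at Bach2, 12 and 13 against 14 and 14 at Lef1 and 9 and 12 against 11 and 13 at S1pr1. T cell identity genes held 31 and 30 regions, among them 5 WT-only regions at Bcl11b (18 and 20 summits against 12 and 13). Fyn had 16 and 19 against 22 and 20, and Cd8b1 6 and 8 against 8 and 5.

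Genes of the MAP kinase pathway, on which PAC1 acts, held 4 KO-only and 4 WT-only regions. Elk3 had 3 and 7 summits in WT and 5 and 6 in Pac1-/-, Spred2 5 and 4 against 6 and 4, Map3k8 2 and 5 against 6 and 6 and Dusp4 2 and 5 against 2 and 1. With summits of score 5 or more alone the direction at Map3k8 turned, and with summits within 50 kb the counts at Dusp4 did not differ. NuRD and deacetylase genes held 3 and 3 regions. Hdac4 had 3 KO-only regions and 1 WT-only region (4 and 6 summits against 6 and 6), and Mta3 had 4 and 7 summits against 5 and 5. Neither direction held under all alternatives, with log2 values (Pac1-/- to WT) of −0.40 to 0.29 at Hdac4 and −0.25 to 0.43 at Mta3. The acetyltransferase list held 0 and 1 (Kat2b, 2 and 3 summits against 3 and 2). Interferon response genes held 3 and 0 regions (exact test, adjusted p = 0.611), at Usp18, Samhd1 and Oas3. Cell cycle genes held 3 and 4, with 3 WT-only regions at Ccnd3 (8 and 12 summits against 6 and 7) and 1 KO-only region at Mki67 (1 and 1 against 2 and 3). Metabolism genes held 4 and 6 (Hif1a, 6 and 10 summits against 6 and 5; Rptor, 4 and 5 against 6 and 6), and cytokine receptor genes 9 and 7 (Jak1, 13 and 15 against 17 and 13; Tgfbr2, 11 and 17 against 11 and 14).

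Of the remaining markers of other cells, NK cell genes held 3 KO-only regions and 1 WT-only region. Klre1 had no summit in WT and 4 and 2 in Pac1-/-, Cd226 1 and 2 against 6 and 4, Itga2 1 and 1 against 2 and 4, and Khdc1a 2 and 1 against none. Myeloid genes held 2 and 6 regions (Cebpb, 6 and 9 summits against 7 and 6; Fcgr3, 2 and 8 against 3 and 3; Ly86, 3 and 2 against 1 and 1; Adgre1, 1 and 2 against none) and dendritic cell genes 6 and 5, with Runx2 at 2 and 2 against 9 and 7, Itgax at 0 and 1 against 5 and 4, Irf8 at 5 and 7 against 3 and 4, and Tcf4 at 4 and 4 against 2 and 2. CD4 and regulatory T cell genes held 4 and 2 (Nrp1, 3 and 7 against 6 and 9; Ikzf4, 2 and 2 against 1 and 1), erythroid and platelet genes 0 and 0, and non-haematopoietic genes 0 and 1 (Epcam). Housekeeping genes held 0 and 0 regions, with 33.5 ± 2.12 summits in each genotype (SD, n = 2 each).

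Counting summits per gene locus gave the same comparison for every gene. Of 9965 loci with at least 4 summits, the libraries of the genotypes did not overlap at 960 (9.63%), with Pac1-/- above WT at 461 and below at 499, against 282 (2.83%) and 314 (3.15%) in the mixed splits. The loci with the largest excess of KO-only regions were Ubac2 (5 against 1, 16 and 20 summits in WT, 20 and 19 in Pac1-/-), Inpp4b (5 against 1, 8 and 11, 10 and 13), and with 4 against 0 Ube2e3 (5 and 6, 16 and 13), Ift57 (5 and 5, 12 and 10), Dock10 (6 and 5, 10 and 10), Rph3al (4 and 5, 9 and 8), Runx2 and Sgk1 (3 and 3, 7 and 7). The direction at Ubac2 turned with other settings, and the difference vanished at Ube2e3 within 20 kb, at Rph3al with summits of score 5 or more and at Inpp4b by the nearest gene end. The excess of WT-only regions was largest at Gas8 (0 against 9, 19 and 21 summits in WT, 4 and 3 in Pac1-/-), followed by Bcl11b, Gm52481 on Y (14 and 16, 5 and 4), Dad1 (1 against 5, 19 and 18, 12 and 12), Rftn1 (10 and 11, 7 and 5), Mtss1 (7 and 10, 1 and 2), Pax5 and Ets1 (27 and 31, 23 and 20). The most summits in all were at Ets1 (101), Foxp1 (95), Prkcq (83), Prex1 (80), Bach2 (79), Fyn (77), Ubac2 (75) and Akap13 (72). Of these, Akap13 (15 and 20, 18 and 19) turned direction without WT replicate 1.

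Limma called 761 loci (348 higher and 413 lower in Pac1-/-, adjusted p under 0.05), and 1 and 0 loci in the mixed splits, but 0 without either WT replicate and 57 and 66 without a Pac1-/- replicate. The fits with a replicate left out tested only 3907 to 4093 loci, because the limit of 4 summits was kept over fewer libraries. On simulated libraries with no change limma called 240 of 9159 loci, so its calls do not hold the stated error rate and no p for a single locus is given. The balance of higher and lower calls turned with some settings. It was 333 and 233 with pseudocount 1 and 76 and 49 with at least 8 summits. Its 10 loci of smallest p each had no summit in 1 of the genotypes. Car5b (3 and 4), Cd163l1 (5 and 4), Itga1 and Klre1 had summits in Pac1-/- alone, and Ankrd6 (4 and 3), Pax5, Ctsh (3 and 3), Dnase1l3 (3 and 3), Bhlhe41 (2 and 4) and Zfp608 (2 and 4) in WT alone. Of 31 effector loci tested it called 13 higher and 0 lower, and adjusted over the list alone 15 higher and 1 lower. Of 13 B cell loci it called 1 higher and 9 lower, and adjusted over the list alone 1 and 10. The set test camera, with a preset correlation of 0.01, called the effector list (mean log2 0.58), the B cell list (mean log2 −1.43) and the NK cell list (mean log2 0.98). With an estimated correlation the limma camera test called none (adjusted p = 0.521, 0.107 and 0.194). Camera also called 6 and 10 lists in the mixed splits, so its calls carry no weight here.

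The strongest KO-only regions had a WT summit nearby. Of the 10 KO-only regions with the highest scores, each had a WT summit within 1061 to 2671 bp. Of these, 4 lay inside Zeb1, Cd53, Spata13 and Gpr146, and others 882 bp from Sp1, 1847 bp from Bhlhe40, 2476 bp from Dusp2 and 127 bp from Astl, the neighbour of Dusp2. The remaining pair lay far from their nearest genes, 72773 bp from Dph5 and 168965 bp from Ets1, the last beyond the limit for a locus. At Sp1 on chromosome 15 the KO-only region at 102405416 to 102405453 (scores 479 and 396) lay 1089 bp from the WT-only region at 102406542 to 102406572 (scores 500 and 667). Of the 10 strongest WT-only regions, the one at Sp1 and one at chromosome 14, 19418851 to 19418852 (scores 1525 and 590) stood apart from the rest, which all lay in the first 100 kb of assembled chromosome 9. Among KO-only regions with no WT summit within 5 kb, a selection made after the values were seen, the 10 strongest included regions inside Zc3h7a (scores 56.1 and 42.3), Klrk1 (19.1 and 27.6), Ggh, Cxcr6 (21.7 and 18.5), Myo16 and Trim16. Others lay 1273 bp from Vmn2r87, 12541 bp from Ccl6, 53498 bp from Slc17a6 and 265697 bp from Btg1. WT-only regions with no Pac1-/- summit within 5 kb and a gene within 100 kb ranked higher, and the strongest lay 7592 bp from Tmem196 (scores 152 and 428), 11983 bp from Gm14496 (62.3 and 126) and inside Fam169b (78.6 and 89.4). The 10 strongest of them had mean score percentiles of 54.6 to 88.1, against 39.5 to 56.4 for the KO-only ones. The KO-only set was not limited to regions near a gene, so these ranges come from unlike filters.

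A stretch beyond Id2, which encodes an inhibitor of helix-loop-helix factors that effector CD8+ T cells need, was singled out after its values were seen. Id2 lies at chromosome 12, 25093799 to 25096092. Between 25213602 and 25394864 lay 10 KO-only regions and no WT-only region, with mean summit positions 117540 to 298343 bp from the gene. Summits nearest to Id2 within 500000 bp numbered 7 and 7 in WT and 19 and 19 in Pac1-/-. Lying over 100 kb from the gene, none of these regions entered the count of the effector list, where Id2 itself had 6 and 5 summits in WT and 5 and 4 in Pac1-/-.

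**Figure D5:**
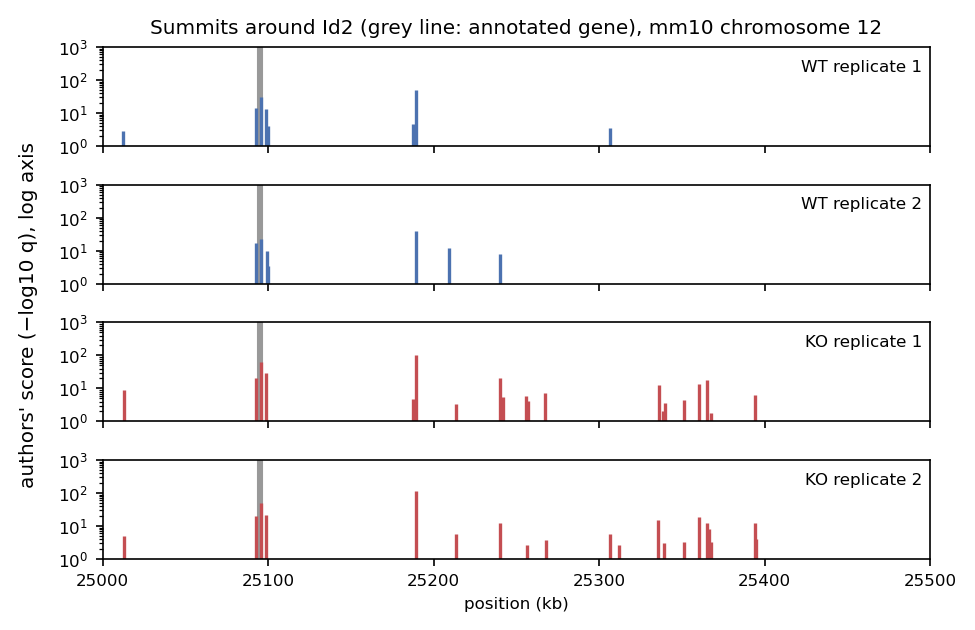
Position (kb, mm10 chromosome 12) and authors' score (−log10 q, log axis) of each summit around Id2, 1 panel per library, with the annotated gene as a grey line. Most summits beyond 25213602 are in the Pac1-/- panels, where 10 regions are shared by both libraries and absent from WT.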

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

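The test in this part was chosen after its result was seen. Summits on the unplaced contig JH584304, which no comparison above used, numbered 37 and 38 in the WT libraries and 6 and 8 in the Pac1-/- libraries, 37.5 ± 0.707 against 7 ± 1.41 (SD, n = 2 each). All contigs outside the main chromosomes together held 56.5 ± 3.54 and 13 ± 1.41.

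The first 100 kb of assembled chromosome 9 followed the same split, with 24 and 22 summits in WT and 2 and 2 in Pac1-/-. The highest scores there were 917 and 873 in WT against 8.95 and 18.7. Of 18 regions in this stretch, 15 were WT-only. A candidate explanation is that input subtraction or library handling differed between the genotypes, which predicts a signal that follows the genotype in all 4 libraries, and it did (15 WT-only regions). A difference of genotype predicts the same, so the explanations cannot be told apart without the input libraries, which were not used here. Summits on Y numbered 21 and 27 in WT and 9 and 8 in Pac1-/-. The Y genes Kdm5d, Eif2s3y, Uty and Ddx3y each had 1 summit in or within 2 kb in every library, so Y was present in all 4. The WT excess at Gas8, at Gm52481 on Y and at chromosome 14, 19418851 to 19418852, followed the genotype as well. Whether it shares a cause with the start of chromosome 9 was not tested.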

How the results depend on the processing

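Alternatives chosen after the data were seen were the limma settings without trend or robust, their pairings with a limit of 8 summits, the assignments by gene end and to 500 kb, the limit to regions near genes, and for the list test the loss of a replicate, the 5 kb rule, score 10, the top 10000 summits, autosomes and presence at score 5. Limits here come from lists of unknown depth with 2 libraries a side. The planned motif alternatives were not run.

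Under all 13 alternatives the effector list kept its call (log2 odds 1.85 to 5.504) and with each replicate left out (1.68 to 2.89). The B cell list kept it in 11 (log2 odds −5.19 to −4.30; −5.68 to −3.33 with a replicate left out) and lost it with the top 10000 summits (−2.65) and with presence at score 5 (−3.56), which leave 3 and 7 regions, so 1 list was called in each.

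KO-only, WT-only and total regions numbered 627, 585 and 1212 with 2500 bp windows, 369, 422 and 791 with the top 10000 summits, 662, 633 and 1295 with no other summit within 5 kb, and 457, 598 and 1055 with presence at score 5. Score 10 left 793 KO-only and 505 WT-only of 1298, so the near balance of the main counts depended on the score limit. Scores were not scaled between libraries, so a fixed limit may cut the lists unequally. With a replicate left out they ranged from 1419 to 2172, 1490 to 2971 and 3475 to 4390, since 1 library then stands for a genotype; without WT replicate 1 WT-only regions numbered 2971. Gene-end genes ranged from 143 to 184 (Pac1-/-) and 204 to 292 (WT). The similarity difference was 0.0567 (2500 bp), 0.0846 (equal length) and 0.061 (top 10000), and 0.0504 to 0.104 with a replicate left out. The gene-end odds ratio lost its call with 250 bp windows (0.819), the top 10000 summits (0.851) and 1 kb (0.833). The cause was not tested.

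With the replicate number as a block limma called 363 loci, and 372 regions followed the replicate number. Differences between replicates 1 and 2 correlated at 0.0036 between the genotypes over 9965 loci. No pairing by replicate number was visible in these counts, which does not exclude a pairing in the design. Limma called 421 loci without scaling, 125 with at least 8 summits, 1203 at score 5, 327 robust and 503 robust without trend, and with at least 8 summits 101 without trend, 188 robust and 75 with both; the last 5 and the fit without trend (667) were tried because of the false calls on simulated data, and none was chosen for its calls. Mixed splits gave up to 76 calls without scaling, 68 at equal length and 64 with pseudocount 1. Fits with a replicate left out tested 3907 to 4093 loci instead of 9965, so their calls do not come from the same loci. With a replicate left out limma called 0 to 66, with 0 lacking either WT replicate (1174 and 1074 at unadjusted p under 0.05); the lone sample is assumed to vary like the other group. Camera called 0 lists with an estimated correlation, 6 at score 5 and 1 to 3 with a replicate left out.

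Directions (log2, Pac1-/- to WT) turned at score 5 for Ubac2 (−0.092), Dusp2 (−0.24) and Map3k8 (−0.18), and by gene end for Ubac2 (−0.39) and Tox (−0.22). Values at Prex1 (0.0013), Stat4 (0.0013), Rph3al (0.0013) and Tnfrsf1b (0.0013) at score 5, at Dusp4 within 50 kb (0.0235), at Dusp4 (0.0235), Ube2e3 (0.0235) and Cd44 (0.0235) within 20 kb, and at Inpp4b by gene end (0.0235), are those that scaling gives any locus with equal counts, so the difference there vanished. Leaving out WT replicate 1 moved the median of all loci to 0.10. With a replicate left out values ranged from −0.192 to 0.033 at Prkcq and −0.161 to 0.0673 at Prex1, where values above 0 lay under that shift or the 0.04 without KO replicate 1, and from −0.0067 to 0.24 at Akap13, which turned. Another 57 list genes are given without a test, a treatment chosen after sign changes were seen; 48 of their 1166 fits, in 26 genes, had another sign, and 29, in 16 genes, lay on the other side of the median of all loci, and 25, in 18 genes, at it. The cause was not tested.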

Other observations

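Tests in this part chosen after their result was seen are those of T cell share, of naive or memory cells and of non-specific extra summits. The windows below were picked from the data. The test of non-specific summits replaced one whose result had been seen, which set 71 and 18 summits (WT, Pac1-/-) at B cell loci against 21 and 14 at non-haematopoietic and erythroid loci (odds ratio 2.61, 95% interval 1.13 to 6.04, Fisher's exact p = 0.0386).

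Genotype-specific regions were counted in windows of 500 kb, and the windows leaning most each way are given. Whether the regions cluster was not tested. After the 10 regions beyond Id2, the windows leaning most to Pac1-/- held the killer lectin-like receptor genes of chromosome 6 from 129500001 (6 KO-only and 0 WT-only regions), Fasl (7 and 2), Gzma and Gzmk (6 and 1), Themis and Ptprk (5 and 0), Ubac2 and Gpr183 (5 and 0) and Cxcr6 with Ccr1 and Ccr9 (5 and 0). Those leaning most to WT, after the start of chromosome 9, held Gas8 on chromosome 8 (0 and 13), Spib (0 and 6), Pax5 (0 and 5) and Gm52481 on Y (0 and 5). These counts are of whole windows, most of which hold other genes too. Spib was assigned 2 of the 6 WT-only regions of its window, and Fasl 4 of the 7 KO-only regions of its own.

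Effector loci held more summits in the Pac1-/- libraries. Longer Pac1-/- lists are argued against, since without WT replicate 1 both are shorter than the remaining WT list and the odds ratio was 6.597 (95% interval 3.382 to 12.87, Fisher's exact test, adjusted p = 2.41e-08); at equal length it was 8.506 (2.81 to 25.75, adjusted p = 3.711e-05), a setting that shortens WT replicate 2 most. A lower share of T cells in WT is argued against only as a loss spread evenly over T cell loci. The effector list leaned to Pac1-/- more than the T cell identity list (odds ratio 6.563, 2.167 to 19.87, Fisher's exact p = 0.0002828). Sites of these lists were not matched by score, so a loss limited to weak sites stays open. B cell marker loci, with 35.5 ± 2.12 summits in WT and 9 ± 1.41 in Pac1-/-, go with a lower share in WT, and NK cell marker loci went the other way. More naive or memory-type cells in WT may contribute and stay open, because the memory list gave an odds ratio of 1.066 (0.6173 to 1.839), an interval that decides neither way. NK cell marker loci also held more summits in Pac1-/-, 19.5 ± 3.54 against 12.5 ± 0.707 in WT (SD, n = 2 each). Only 7 of the 12 NK cell genes had a summit in any library. Both Pac1-/- libraries were above both WT libraries at 3 of these 7 and below at 1, and 3 overlapped. A different mixture of sorted cells was not tested and stays open. The difference of genotype itself stays open too and was not tested.

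B cell marker loci held more summits in WT, although a sort for CD8+ T cells should remove B cells. Extra WT summits spread evenly over genes are argued against as the whole cause, since that spread forbids the odds ratio of 31.03 (1.854 to 519.3) for B cell against other genes, which is the inverse of the list result and supports no other explanation. B cells in the WT samples are a candidate explanation: a second list of 22 genes, fixed before its values were seen, held 54 and 66 summits in WT and 36 and 39 in Pac1-/- (log2 ratio 0.6481), with 14 WT-only and 4 KO-only regions (odds ratio 3.21, 1.11 to 9.28, exact p = 0.03024). That list includes Cd74 and MHC class II genes and does not separate B cells from other antigen-presenting cells, and in the first list Cd79a had 2 and 1 summits against none, Cd79b 1 and 3 against 0 and 1 and Ms4a1 0 and 1 against none. Of the 18 markers 5 had a summit in both Pac1-/- libraries and 0 were in another list, and a change within WT T cells was not tested.

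Regions from 50 kb to 5 Mb around Dusp2, where DNA carried along with the targeted allele would lie, were genotype-specific in 15 of 134 cases, against 2137 of 23494 elsewhere (odds ratio 1.296, 95% interval 0.7621 to 2.204, Fisher's exact p = 0.3673), which leaves the question open. KO-only regions were at gene ends less often than WT-only regions also at equal list length (odds ratio 0.7034, 0.5571 to 0.8882, exact p = 0.00361). These are nearly the same lists as in the main comparison, so this decides nothing about a hypothesis that sites gained without PAC1 are distal, and with the top 10000 summits the ratio was 0.851 (exact p = 0.296).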
